A study of Mus musculus with 15 samples.

How the data were processed

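RNA was measured in whole colon of C57BL/6 mice, an inbred laboratory strain. The mice were wild type (WT) or littermates with a human IL26 bacterial artificial chromosome transgene (TG), a long piece of human DNA carried in the mouse genome. Interleukin-26 is a cytokine of the IL-10 family for which mice have no gene. Per the protocol, control mice were taken at 20 to 24 weeks of age, and the others at 10 to 14 weeks after 6 days of 2.5% dextran sulfate sodium (DSS), a polymer that injures the colon lining. DSS and age therefore cannot be told apart in these samples. Animals of both sexes were used per the protocol, and the sex, cage and litter of each animal are not given in the sources used here. Libraries were enriched for messenger RNA, made with a strand-specific kit (NEBNext Ultra Directional) and sequenced on a NovaSeq instrument. Mice given an antibody against IL-26 or an isotype control are not analysed here.

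The deposited table holds expected counts, 1 value per gene and library, that the authors made by trimming reads with cutadapt, aligning them to the mouse genome mm10 with STAR and counting them with featureCounts. The versions, the strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Of all values, 83.5% were whole numbers within a tolerance of 0.005, and 53.0% of genes had only whole values; the rest fell mostly on simple fractions, so some reads had been shared out in equal parts. Counts were not scaled for depth and were rounded to whole numbers for the count tests. Genes are named by the symbols of the table, with the chromosome, start and end given there. The table has 23420 genes, of which 3383 had no counts. Among tested genes, 53 had the same counts as another gene in all libraries, and 27 symbols had the form of a date. The table has no row for human IL26, so the transgene itself was not measured. It also has none for the mitochondrially encoded messenger RNAs.

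All 15 libraries were used, in 4 groups: 4 WT control, 4 TG control, 3 WT DSS and 4 TG DSS. Total counts per library ranged from 26506483 to 47207943. Low-count genes were removed with filterByExpr of edgeR by group, which left 16693 genes and took out 6727. Libraries were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood model with a mean per group was fitted to all 15 libraries with edgeR 4.0.16 in R 4.3.3. The common biological coefficient of variation was 0.196, with 11 residual degrees of freedom. Quasi-likelihood F tests compared TG with WT without DSS, TG with WT after DSS, DSS with control in each genotype, and the DSS response between genotypes (the interaction). P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p below 0.05. Standard errors (SE) of log2 changes come from the same fit. Group values are CPM (counts divided by the scaled library total, times 1e6) as mean ± SD. No covariate was used.

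On simulated data with the spread of each gene in these libraries, 200 of 16693 genes were changed by 1.5-fold, 2-fold or 4-fold. Each gene was drawn independently around its mean over all 15 libraries. Apart from the changes made, the simulation had no DSS effect and no structure that genes share across libraries. The real libraries have such structure, so the rates below need not hold for them. The model recovered 31.3% to 38.8% of genes at 1.5-fold, 61.2% to 74.6% at 2-fold and 86.4% to 93.9% at 4-fold, with 1 to 7 false calls per comparison. A gene with no counts in a group is given a fold against a floor of 3 counts over the group, as a lower bound. With 1 to 3 counts, the ratio is given with its 95% counting interval (exact, from the binomial distribution). Amplified reads are not independent molecules, so these bounds cover counting error only.

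Gene lists for cell types, tissues and pathways were fixed from textbook knowledge: 38 lists, of which 36 had at least 3 tested members. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, which asks whether the list moves more than other genes, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The median estimated correlation over lists was 0.350 to 0.401 by comparison, far above the preset, so adjusted p at the preset can be far too small. Fry asks whether the genes of a list move, on balance, in 1 direction, and it compares them with no other genes. A list's score in a library is the mean log2 CPM of its tested members, with a prior count of 2. Older symbols were matched by name (Emr1 for Adgre1, Chi3l3 for Chil3, Igj for Jchain and others), and members with no row (such as Ly6g and the immunoglobulin constant genes) were left out. The goblet cell gene now called Clca1 was matched by its genome position, where the table has Clca3. This match was corrected after the values had been seen. Matched by symbol instead, the list's adjusted p was 0.959 and not 0.636 for TG against WT in controls, 0.00081 and not 3.58e-05 after DSS, 0.826 and not 0.277 for DSS in WT, 0.0387 and not 0.0570 for DSS in TG, and 0.000843 and not 1.99e-05 for the interaction.

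The groups, comparisons, tests, lists, first set of alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule names up to 10 genes per direction with the largest log2 change. These had to pass the test, reach a mean of 1 CPM in 1 of the groups, and have no overlap between the libraries of both groups. Gene models without a proper name and single immunoglobulin or T cell receptor segments were left out. The rule also names up to 4 members per list with the smallest p, the receptor genes Il10ra, Il10rb and Il20ra, and sex-linked markers. Some genes that the rule names are not reported here. Genes named otherwise are said to have been chosen after their values were seen.

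Alternatives were other scalings (RLE and upper quartile), no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit to only the groups compared, a robust dispersion, covariates (Xist level, smooth muscle score, 1 surrogate variable from sva 3.50.0) and leaving out each library in turn. 4 more settings were added after the data were seen: without the libraries lacking Xist, without those with clock gene Dbp above Arntl, an adipose score as covariate, and genes with identical counts taken once. Agreement between comparisons was measured across all tested genes by Pearson and Spearman correlation. Other splits of the libraries were counted, all 35 for each pair of groups and 100 random draws for the interaction and the correlations. Pairs of libraries from 1 group were checked for duplicates: their chi-square per degree of freedom was 21.0 to 97.3, far above that of repeated counting of 1 library.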

Results

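Messenger RNA was measured in the colon of 15 mice: 4 WT control, 4 TG control, 3 WT DSS and 4 TG DSS. TG mice carried a human IL26 transgene, and DSS is a polymer that injures the colon lining. Expected counts per library summed to 36278478 to 47207943 in WT controls, 31196038 to 40026109 in TG controls, 32625889 to 40001003 in WT DSS and 26506483 to 31940575 in TG DSS. The first principal component of the 500 most variable genes held 59.6% of their variance and separated all DSS from all control libraries. The second held 12.1%. Xist, the RNA of the inactive X chromosome, was near 0 in WT control 4 and WT DSS 10, at 0.318 and 0.149 CPM, and at least 500.5 CPM in the other 13 libraries. The Y-linked gene Ddx3y was at 57.9 and 66.2 CPM in those 2 libraries and at 0 in the others. By these markers those 2 WT libraries came from males and the other 13 from females, so all TG libraries were female. Dbp, a gene with a daily rhythm, exceeded Arntl in WT control 4, TG control 14, WT DSS 10 and TG DSS 19. Adipose genes differed widely between libraries, with scores from -1.04 in TG control 14 to 6.84 in TG control 11 (mean log2 CPM). Both TG comparisons changed few genes, and both DSS comparisons changed many.

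**Figure D1:**
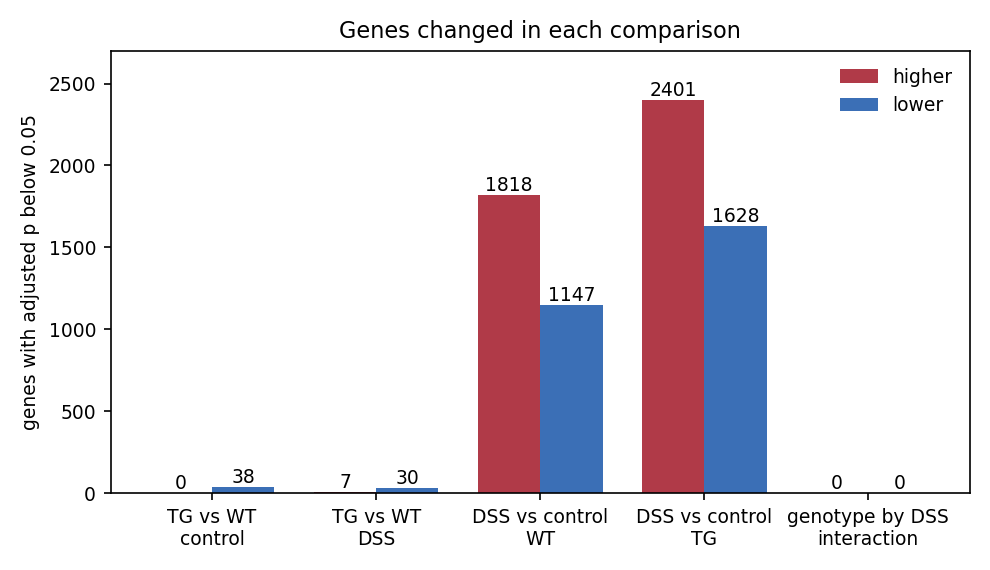
Number of genes with an edgeR adjusted p below 0.05 (vertical axis) in each comparison and in the interaction, with red bars for higher and blue bars for lower genes. DSS against control gave 2965 genes in WT and 4029 in TG mice, and DSS and control mice also differed in age. TG against WT gave 38 genes without and 37 with DSS. With DSS, another split of the same libraries gave 229.

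Without DSS, the comparison of TG with WT mice asked what the transgene alone does to the colon at 20 to 24 weeks. Genes of B cells and lymphoid follicles were lower in TG mice. Cd22, an inhibitory receptor of B cells (chromosome 7, 30865404 to 30880342), fell from 10.8 ± 4.25 to 1.76 ± 0.842 CPM (SD, n = 4 and 4), a log2 change of -2.61 (SE 0.39, edgeR adjusted p = 0.0175). The homing receptors Ccr7 (chromosome 11, 99144199 to 99155077) and Cxcr5 (chromosome 9, 44511787 to 44526421) had log2 changes of -2.66 (SE 0.41, adjusted p = 0.0195) and -2.14 (SE 0.40, adjusted p = 0.0467). Among class II antigen presentation genes on chromosome 17, H2-Eb2, H2-Oa and H2-DMb2 changed by -2.62 (SE 0.47), -2.33 (SE 0.41) and -2.13 (SE 0.36), with adjusted p of 0.0386, 0.0386 and 0.0353. Further lower genes were the lymphocyte receptor Gpr174 at -2.67 (adjusted p = 0.0377), the retinol transporter Stra6 at -2.13 (adjusted p = 0.0386) and the leukocyte receptor Treml2 at -2.09 (adjusted p = 0.0392). In each of the 9 genes given so far all 4 TG libraries were below all 4 WT libraries. Lymphotoxin beta (Ltb), which organises lymphoid tissue, fell by 1.72 (SE 0.33, adjusted p = 0.0478). Clusterin (Clu), a secreted chaperone, fell from 84.1 ± 15.5 to 29.4 ± 6.05 CPM (log2 change -1.51, SE 0.29, adjusted p = 0.0467). The pan-leukocyte genes Cd52 and Coro1a, chosen after their values were seen, had the smallest adjusted p, 0.000509 and 0.00557, at log2 changes of -1.08 and -1.19.

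Of 16693 genes, 38 were lower in TG controls and 0 were higher by edgeR, 28 of them by at least 2-fold. An unadjusted p below 0.05 was found for 1095 genes, against 834.65 by chance. Of the 34 other splits of these libraries 3 gave as many, up to 1626, so this excess does not set the genotypes apart. The groups did not overlap in 839 genes (5.03%), against 2.86% by chance. DESeq2 called 195 genes and limma-voom 2. With the smooth muscle score as covariate 1 gene was called, and with the adipose score, a setting added after the data were seen, 6. The count was 8 without WT control 2, 3 without WT control 3, 3 without WT control 4, 2 without TG control 11, 1 without TG control 12 and 3 without TG control 13. The 9 genes given above from Cd22 to Treml2 passed in 0 to 3 of the 8 fits that left out 1 control library, with adjusted p up to 0.205 over all settings, and kept their direction.

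Of the 15 tested genes of the B cell and follicle list, 4 were lower over all genes and 14 were lower adjusted over the list alone, with a median log2 change of -2.61. The list was lower by camera (adjusted p = 3.73e-52) and also with an estimated correlation (adjusted p = 0.0148). All 7 genes of class II presentation were below 0, with 1 called over all genes (H2-Eb1, from 151 ± 24.5 to 92.5 ± 6.49 CPM) and 7 adjusted over the list alone. That list's median was -0.71 (camera adjusted p = 1.54e-18, or 0.0492 with an estimated correlation). The 23 T and NK lymphocyte genes all lay below 0, with 0 called over all genes, 3 adjusted over the list alone and a median of -0.59 (camera adjusted p = 4.64e-14, or 0.0743 with an estimated correlation). Lower by camera only were epithelial antimicrobial defence (median -0.27, adjusted p = 0.000331, or 0.101 with an estimated correlation), posterior position genes such as Hoxb13 (median -0.94, 0.005002 and 0.506) and inflammatory cytokines (median -0.20, 0.0146 and 0.765).

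Higher by camera only were smooth muscle (12 of 12 genes above 0, median 0.35, adjusted p = 2.52e-07, or 0.506 with an estimated correlation), fatty acid oxidation (18 of 19 above 0, median 0.15, 0.000202 and 0.552) and adipose tissue. Adipose genes such as Adipoq had a median of 3.63 with 0 called over all genes and 7 adjusted over the list alone (camera adjusted p = 6.23e-06, or 0.506 with an estimated correlation). Their score was 6.84, 3.25 and 5.402 in TG control 11, 12 and 13 but -1.04 in TG control 14. A further 4 calls by camera were lost when 1 library was left out. Interferon-gamma targets (median -0.12, adjusted p = 0.0355) rose to an adjusted p of 0.374, 0.273, 0.289 and 0.0556 without WT control 3, TG control 11, TG control 12 and TG control 13. Neutrophil genes (median -0.39, or -0.30 with a member at 0 counts taken at its bound, adjusted p = 0.0222) reached 0.339 without WT control 4 and 0.0647 without TG control 11. The unfolded protein response (median -0.19, adjusted p = 0.0109) reached 0.740, 0.0981 and 0.209 without WT control 4, TG control 11 and TG control 12. Red blood cell genes (median 0.72, adjusted p = 0.0109) reached 0.0931, 0.0981 and 0.0775 without WT control 4, TG control 11 and TG control 13. With an estimated correlation these 4 lists had adjusted p of 0.765, 0.765, 0.765 and 0.552.

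The remaining 23 lists were not called in controls. By camera the adjusted p was 0.0608 for IL-10 family genes, 0.0746 for STAT3 targets, 0.0700 for macrophages, 0.0676 for plasma cells, 0.0608 for matrix remodelling and 0.497 for type I interferon-stimulated genes (median 0.12). Those genes were called higher without WT control 3 (5.58e-08) and without TG control 12 (0.0363) and lower without TG control 14 (0.000434). It was 0.636 for absorptive colonocytes, proliferation, cholesterol biosynthesis and circadian clock genes, 0.299 for tuft cells, 0.279 for tight junctions, 0.407 for xenobiotic metabolism, 0.419 for endothelium, 0.349 for enteric neurons and glia, 0.196 for small intestine and 0.203 for immediate early genes. Goblet cell genes had a median of 0.02 and a mean of -0.12, mast cell and eosinophil genes 0.0021 and -0.07, enteroendocrine genes 0.01 and -0.03, and regenerating epithelium 0.09 and -0.17, each with a camera direction of down and adjusted p of 0.636, 0.636, 0.572 and 0.299. Pancreas genes had a median of 0.31 and a mean of 0.06 and crypt stem cell genes -0.01 and -0.01, and in both the test had the opposite sign (adjusted p of 0.892 and 0.898). With 1 library left out, camera called IL-10 family genes (0.0237 without WT control 1, 0.0075 without TG control 13), STAT3 targets (0.0389 without WT control 1, 0.0226 without WT control 2, 0.0179 without TG control 14) and macrophages (0.0389 without WT control 1, 0.044 without WT control 3, 0.00385 without TG control 13). It then also called plasma cells (0.0379 without WT control 2, 0.0213 without WT control 3, 0.0188 without TG control 11), enteroendocrine cells (0.0235 without TG control 14) and xenobiotic metabolism (0.021 without TG control 11). Called in such fits too were matrix remodelling (0.0389 without WT control 1, 0.0336 without WT control 2, 0.000306 without TG control 14), endothelium (0.0179 without TG control 14) and small intestine (0.0459 without WT control 2, 0.0197 without TG control 14). The rest were circadian clock (0.0491 without WT control 4). The chains of the putative IL-26 receptor and the related Il10ra did not pass: Il10rb changed by -0.04 (SE 0.07, adjusted p = 1), Il20ra by 0.55 (SE 0.96, adjusted p = 1) and Il10ra by -0.55 (SE 0.17, adjusted p = 0.305). Il22ra2, the decoy receptor of interleukin-22, was at -1.75 (SE 0.40, adjusted p = 0.0943).

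**Figure D2:**
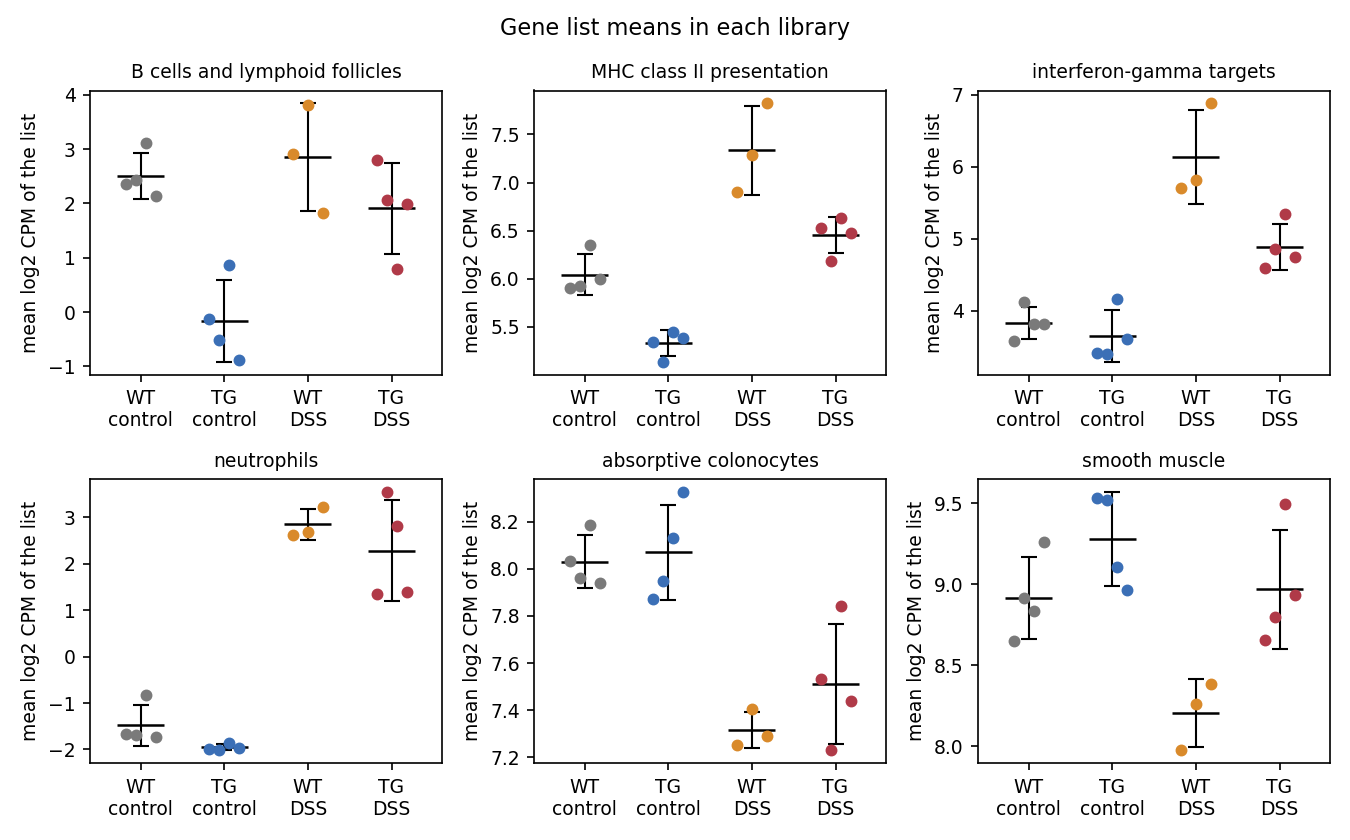
Mean log2 CPM of the tested genes of 6 lists (vertical axes) in each library by group, with points for libraries and bars for the group mean ± SD. B cell genes averaged -0.16 in TG control against 2.51 in WT control, and interferon-gamma targets averaged 4.88 in TG DSS against 6.13 in WT DSS.

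After DSS, the comparison of TG with WT mice asked whether the transgene changes the colon during injury. Interferon-gamma targets were lower in TG mice by camera at its preset correlation, with 3 of 21 genes called, but not with an estimated correlation (adjusted p = 0.240). The goblet cell product Ang4 was far higher. Trim10, a ubiquitin ligase family gene (chromosome 17, 36869574 to 36877833), was at 5.18 ± 0.729 CPM in WT and 0.716 ± 0.240 CPM in TG mice (n = 3 and 4), a log2 change of -2.84 (SE 0.36, edgeR adjusted p = 0.00298). Socs1, an inhibitor of cytokine signalling induced by interferon (chromosome 16, 10783809 to 10785536), fell from 16.2 ± 3.85 to 6.29 ± 0.828 CPM (log2 change -1.37, SE 0.19, adjusted p = 0.00667). The class I-like genes H2-Q7 and H2-Q9 (chromosome 17, 35439155 to 35443773 and 35439167 to 35443770) had the same counts as each other, so they are 1 measurement: 38.9 ± 5.56 CPM in WT and 14.8 ± 0.251 CPM in TG mice (log2 change -1.39, SE 0.13, adjusted p = 0.000215). The chemokine Cxcl9 (chromosome 5, 92321331 to 92328079) fell from 52.5 ± 36.8 to 7.04 ± 3.87 CPM (log2 change -2.89, SE 0.47, adjusted p = 0.0249). The guanylate-binding protein Gbp4 (chromosome 5, 105115767 to 105139586) changed by -2.10 (SE 0.35, adjusted p = 0.0273). The interferon-induced GTPases Tgtp1 and Gvin1 changed by -2.17 (SE 0.39, adjusted p = 0.0383) and -1.36 (SE 0.25, adjusted p = 0.0385). Ltf, which encodes lactoferrin (chromosome 9, 111019292 to 111042766), had a log2 change of -3.69 (SE 0.58, adjusted p = 0.0249), with 136.1 CPM in WT DSS 10 against 18.2 and 26.8 CPM in the other WT libraries. The lymphocyte membrane gene Ms4a4b changed by -1.51 (SE 0.28, adjusted p = 0.0450). Ly6a, a member of the regenerating epithelium list, fell from 1233 ± 193 to 578.9 ± 39.4 CPM (log2 change -1.09, SE 0.18, adjusted p = 0.0273). In whole colon the cells it came from cannot be told.

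Ang4, an antimicrobial ribonuclease (chromosome 14, 51763892 to 51773590), was at 33.1 ± 11.8 CPM in WT and 1291 ± 859 CPM in TG mice after DSS (log2 change 5.29, SE 0.97, adjusted p = 0.0409). Clps, which encodes colipase (chromosome 17, 28558214 to 28560714), was at 7.65 ± 2.16 and 36.2 ± 16.2 CPM (log2 change 2.24, SE 0.36, adjusted p = 0.0249). Smaller rises were found for the neuronal gene Lgi1 at 1.99 (adjusted p = 0.0471), the retinol-binding protein Rbp2 at 1.44 (adjusted p = 0.0301), the GLP-2 receptor Glp2r at 0.79 (adjusted p = 0.0301) and the transporter scaffold Slc9a3r2 at 0.53 (adjusted p = 0.0498). In each of these 6 genes all 4 TG libraries were above all 3 WT libraries. The lectin Itln1 (5.81, adjusted p = 0.0535), Nos2 (-1.80, adjusted p = 0.0520), Irf1 (-0.53, adjusted p = 0.0520) and Tnf (-1.12, adjusted p = 0.0520) did not pass.

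By edgeR, 37 genes changed, 7 higher and 30 lower, with 5 and 20 of them by at least 2-fold. An unadjusted p below 0.05 was found for 3419 genes, a number that 1 of the 34 other splits reached with 3477, and the groups did not overlap in 2598 genes (15.6%), against 5.71% by chance. DESeq2 called 832 genes and limma-voom 95. The count was 61 without WT DSS 6, 79 without WT DSS 7, 11 without WT DSS 10, 8 without TG DSS 19, 11 without TG DSS 21 and 18 without TG DSS 22. Of the named genes, Trim10, H2-Q7, H2-Q9 and Socs1 passed in all 7 fits that left out 1 DSS library, the other 6 lower genes in 2 to 4 and the 6 higher genes in 0 to 3. Trim10, H2-Q7 and H2-Q9, like the class II genes and Ltb lower in controls, lie in the MHC region of chromosome 17. Whether a strain difference or shared reads there play a part was not tested. WT DSS 10, which lacked Xist and had Dbp above Arntl, had the highest Cxcl9 of the WT libraries, 93.7 CPM against 40.9 and 22.8 CPM. Without it the log2 change was -2.18 for Cxcl9, -2.26 for Ltf, -1.24 for Tgtp1, -1.24 for Gbp4 and -0.77 for Gvin1.

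**Figure D3:**
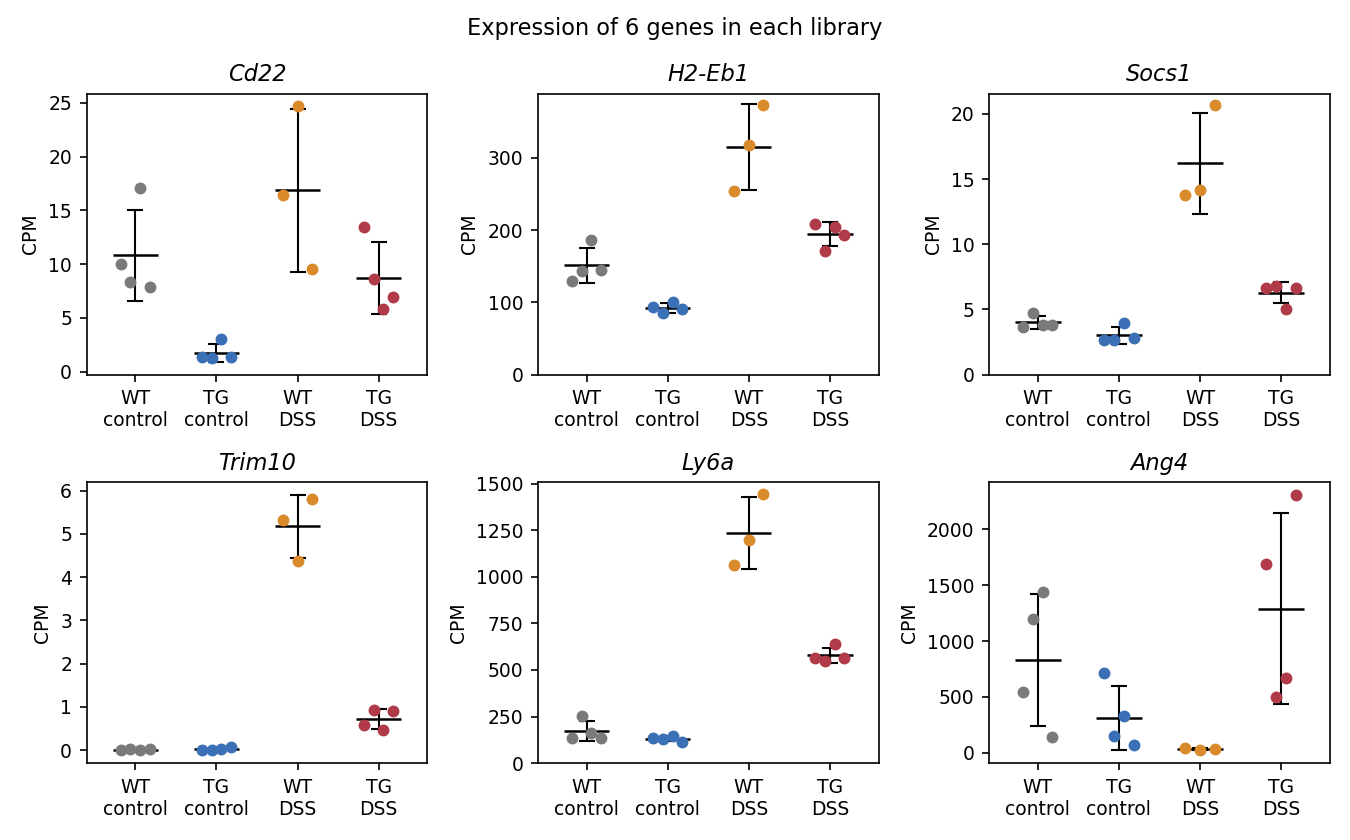
CPM (vertical axes) of 6 named genes in each library by group, with points for libraries and bars for the group mean ± SD. Trim10, Socs1 and Ly6a were lower in all 4 TG DSS than in all 3 WT DSS libraries, and Ang4 was higher.

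Among the 21 interferon-gamma targets, 3 were lower over all genes (Socs1, Cxcl9 and Gbp4) and 20 adjusted over the list alone, with a median of -1.26 (camera adjusted p = 6.04e-21, or 0.240 with an estimated correlation). Class II presentation had 2 of 7 lower over all genes (H2-Ab1 at -0.79 and H2-Eb1 at -0.70), 7 adjusted over the list alone and a median of -0.82 (3.24e-12 and 0.240). The type I interferon-stimulated genes all lay below 0, 21 of 21, with 0 adjusted over the list alone and a median of -0.71 (0.00245 and 0.618). Proliferation genes also all lay below 0, 20 of 20, with 0 called and a median of -0.92 (1.82e-09 and 0.391). In TG DSS 20 the proliferation score was 2.65, against 4.20 to 5.19 in the other TG DSS libraries. T and NK lymphocyte genes had a median of -0.54 with 4 adjusted over the list alone (3.58e-05 and 0.369). The regenerating epithelium list had 1 lower over all genes (Ly6a), 3 adjusted over the list alone and a median of -0.53 (0.000102 and 0.240). B cell genes had a median of -0.9975 and 0 called (0.000377 and 0.556), and without WT DSS 6 the adjusted p was 0.126.

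On the other side, smooth muscle genes had 0 called over all genes, 12 of 12 higher adjusted over the list alone and a median of 0.78 (camera adjusted p = 2.39e-12, or 0.240 with an estimated correlation). Red blood cell genes had 5 of 5 higher adjusted over the list alone and a median of 1.60 (1.34e-06 and 0.240). Goblet cell genes had 4 of 15 adjusted over the list alone and a median of 0.42 (3.58e-05 and 0.240), and tuft cell genes 3 of 9 and a median of 0.50 (0.000810 and 0.253). Endothelium had 8 of 12 adjusted over the list alone and a median of 0.51 (3.58e-05 and 0.391), and enteric neurons and glia 14 of 14 above 0 and a median of 0.67 (9.28e-06 and 0.369). With an estimated correlation 0 of the 20 lists called by camera passed, and fry called 7.

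The other 7 calls after DSS each depended on 1 library or another. STAT3 targets (median -0.16, camera adjusted p = 0.0282) reached 0.0974, 0.197 and 0.250 without WT DSS 6, TG DSS 19 and TG DSS 21. Cytokines and chemokines (median -0.35, 0.00573) reached 0.0842 and 0.239 without TG DSS 19 and TG DSS 21. Cholesterol biosynthesis (median -0.28, 0.00131) reached 0.0520 and 0.104 without WT DSS 6 and TG DSS 20, and the unfolded protein response (median -0.29, 0.00736) 0.0670 and 0.0597 without the same libraries. Without WT DSS 10, fatty acid oxidation (median 0.17, 0.00736) reached 0.255, xenobiotic metabolism (median 0.30, 0.00150) 0.0966 and small intestine genes (median 1.10, 0.00536) 0.0543. Epithelial antimicrobial defence was not called (adjusted p = 0.828): its median was -0.15 and its mean 0.49, with Ang4 higher over all genes and 3 higher and 3 lower adjusted over the list alone. Macrophage genes (median 0.03, mean -0.07) and posterior genes (median -0.03, mean 0.0042) also differed in sign and were not called (0.450 and 0.914). The other lists were not called either: IL-10 family 0.316, neutrophils 0.201, plasma cells 0.464, mast cells 0.203, absorptive colonocytes 0.0711, crypt stem cells 0.883, enteroendocrine cells 0.768, tight junctions 0.464, matrix remodelling 0.253, adipose tissue 0.464, pancreas 0.350, circadian clock 0.203 and immediate early genes 0.828. With an estimated correlation the 7 lists above had adjusted p of 0.556, 0.556, 0.594, 0.594, 0.572, 0.391 and 0.369. With 1 library left out, camera called neutrophils (0.0447 without TG DSS 20, 0.000977 without TG DSS 22), macrophages (0.0376 without TG DSS 20) and mast cells (0.0226 without TG DSS 22). It then also called absorptive colonocytes (0.00691 without TG DSS 22), matrix remodelling (0.00127 without WT DSS 10, 0.00901 without TG DSS 19) and adipose tissue (0.0447 without TG DSS 20). Called in such fits too were circadian clock (0.0147 without WT DSS 10) and immediate early genes (0.00556 without WT DSS 10). Il10rb changed by 0.05 (adjusted p = 0.716), Il20ra by 0.29 (adjusted p = 0.834) and Il10ra by -0.57 (adjusted p = 0.116).

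In WT mice, the comparison of DSS with control asked what the injury does without the transgene, in mice that also differed in age. Genes of neutrophils and of inflammatory cytokines and chemokines rose, and those of epithelial antimicrobial defence went both ways, 10 of 17 higher and 4 lower. S100a8 and S100a9, calcium-binding proteins of neutrophils (chromosome 3, 90669071 to 90670034 and 90692633 to 90695691), rose from 0.205 ± 0.168 to 36.8 ± 2.48 CPM and from 0.322 ± 0.314 to 45.1 ± 10.9 CPM (n = 4 and 3). Their log2 changes were 7.48 (SE 0.77, edgeR adjusted p = 2.30e-05) and 7.13 (SE 0.81, adjusted p = 5.07e-05). Cxcl2, a chemokine for neutrophils (chromosome 5, 90903899 to 90905938), rose by 8.70 (SE 0.98, adjusted p = 4.49e-05), and Cxcl3, with 0 counts in controls, was at least 185-fold higher. The serine protease gene Prss22 had 1 count in controls and a ratio of 1826 (95% interval 327 to 72184). Trim10 had 2 counts in controls and a ratio of 425 (117 to 3516), the neutrophil growth factor Csf3 had 3 and a ratio of 189 (64.2 to 921), and Hemt1 had 1 and a ratio of 219 (38.6 to 8694). Without WT control 4, Prss22 had 0 counts in controls and was at least 469-fold higher, and without WT control 2, Hemt1 had 0 and was at least 56.3-fold higher. The Csf3 ratio was 420 (75.0 to 16650) without WT control 1 and 125 (42.1 to 613) without WT DSS 6. Ltf rose by 7.95 (SE 0.75, adjusted p = 1.24e-05) and AI747448 (chromosome 3, 144910921 to 144932529) by 7.90 (SE 0.64, adjusted p = 3.14e-06). The log2 change was 6.53 for Ltf without WT DSS 10, 9.66 for Cxcl2 without WT control 3, and 8.15 for S100a8 and 7.94 for S100a9 without WT control 4.

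The genes that fell included Mptx1, a pentraxin of the intestinal epithelium (chromosome 1, 174330518 to 174332877), from 4817 ± 3099 to 69.0 ± 26.8 CPM, a log2 change of -6.12 (SE 0.89, adjusted p = 0.000272). Its relative Mptx2, with 0 counts after DSS, was at least 44.7-fold lower, or 29.3-fold without WT DSS 6 and 28.4-fold without WT DSS 10. The antimicrobial products Itln1 and Ang4 changed by -4.90 (SE 1.19, adjusted p = 0.01004) and -4.65 (SE 0.94, adjusted p = 0.00333). Lower too were the muscle myosin Myh2 at -4.76, the lipase-related Pnliprp1 at -4.75, AB099516 at -4.63, Mettl7a2 at -3.996 and the protease Tmprss13 at -3.66, with adjusted p of 0.000742, 0.00348, 0.00346, 0.00363 and 0.0436. Without WT DSS 6, Pnliprp1 was at -8.24 and Tmprss13 at -5.36, and without WT DSS 10, Pnliprp1 was at -4.16 and Myh2 at -5.91. AB099516 and Mettl7a2 overlap on chromosome 15. Apart from Tmprss13, which passed in 2 of 7 fits leaving out 1 library, all named genes passed in all 7.

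Between DSS and control, 2965 genes differed in WT mice, 1818 higher and 1147 lower, of which 870 and 290 by at least 2-fold. The groups did not overlap in 4656 genes (27.9%), against 5.71% by chance. Of 21 interferon-gamma targets all 21 rose over all genes, such as Cxcl9 at 5.04, Ido1 at 5.09 and Iigp1 at 3.65 (median 2.16, camera adjusted p = 1.33e-26, or 0.0428 with an estimated correlation). STAT3 targets had 15 of 16 higher, among them Socs3 at 3.44 and Lrg1 at 4.71 (median 1.70, 1.81e-25 and 0.00804). Cytokines and chemokines had 18 of 21 higher, with Tnf at 3.59 and Il1b at 4.18 (median 3.59, 7.37e-26 and 0.0176). Neutrophils had 11 of 12 higher (median 4.61, 2.75e-16 and 0.0409), macrophages 13 of 16 (median 1.26, 9.50e-19 and 0.0428) and class II presentation 7 of 7 (median 1.31, 1.05e-12 and 0.0428). Epithelial antimicrobial defence had 10 higher, such as Nos2 at 5.86 and Slpi at 4.07, and 4 lower of 17 (median 1.55, 1.82e-07 and 0.0133). Regenerating epithelium had 10 of 14 higher, led by Ly6a at 2.85 (median 1.24, 5.70e-12 and 0.0133). Absorptive colonocyte genes had 9 of 20 lower, such as Sult1a1 at -1.73 and Car2 at -1.03 (median -0.74, 5.10e-06 and 0.0428). Adjusted over the list alone, these counts were 21, 15, 20, 12, 15, 7, 10 higher and 4 lower, 11 and 9 in the same order.

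Called by camera but not with an estimated correlation were IL-10 family genes (7 of 10 higher over all genes, median 0.98, adjusted p = 0.00273 and 0.125), T and NK lymphocytes (9 of 23 higher, median 0.93, 3.01e-05 and 0.247), matrix remodelling (7 of 19 higher, such as Mmp3 at 6.24, median 0.79, 2.67e-07 and 0.302) and red blood cells (4 of 5 higher, median 1.998, 2.74e-05 and 0.142). Lower in this way were smooth muscle (7 of 12 lower, median -0.72, 7.32e-06 and 0.325), xenobiotic metabolism (11 of 22 lower, median -0.71, 3.44e-05 and 0.199) and crypt stem cells (4 of 13 lower, such as Lgr5 at -2.46 and Axin2 at -1.60, median -0.61, 0.00178 and 0.247). Adjusted over the list alone the counts were 7, 12, 14 and 4 higher and 10, 12 and 4 lower. A further 4 calls were lost without 1 library. Type I interferon-stimulated genes (median 0.60, 0.0181) reached 0.0630, 0.0783 and 0.0860 without WT control 2, WT control 4 and WT DSS 10. Fatty acid oxidation (median -0.26, 0.0112) reached 0.119 and endothelium (median 0.37, 0.00889) 0.0771 without WT DSS 10. Immediate early genes (median 0.23, 0.0211) reached 0.0880 without WT DSS 6 and 0.232 without WT DSS 7. With an estimated correlation these 4 had adjusted p of 0.741, 0.539, 0.539 and 0.479. Not called were B cells (0.233), plasma cells (0.544), mast cells (0.0856), goblet cells (0.277), tuft cells (0.344), proliferation (0.844), the unfolded protein response (0.109), enteric neurons and glia (0.232), adipose tissue (0.759), pancreas (0.0899), small intestine (0.0856) and circadian clock genes (0.277). Enteroendocrine genes (median -0.17, mean 0.04), cholesterol biosynthesis (0.01 and -0.03) and posterior genes (0.0011 and -0.31) were not called (0.949, 0.626 and 0.644) and differed in sign, and tight junctions (0.11 and 0.01, adjusted p = 0.844) differed in sign from their test. With 1 library left out, camera called B cells (0.0097 without WT DSS 10), mast cells (0.0416 without WT DSS 7) and unfolded protein response (0.00264 without WT control 4). It then also called enteric neurons and glia (0.00358 without WT DSS 10) and small intestine (0.0412 without WT control 2, 0.0416 without WT DSS 7). The receptor genes Il10ra, Il20ra and Il10rb rose by 1.35 (adjusted p = 0.000125), 2.98 (adjusted p = 0.0212) and 0.25 (adjusted p = 0.0402).

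In TG mice, the same comparison of DSS with control asked what the injury does in the presence of the transgene. Of the lists, 11 of 12 neutrophil, 19 of 21 cytokine and 12 of 15 B cell genes rose, but with an estimated correlation these lists did not pass (adjusted p of 0.06925, 0.05753 and 0.2095). Mmp8, a collagenase of neutrophils (chromosome 9, 7558429 to 7568486), had 0 counts in controls and was at least 179-fold higher at 3.75 ± 4.36 CPM (n = 4). The neutrophil granule gene Ngp, the barrier cytokine Il22 and the receptor gene Tarm1 also had 0 counts in controls and were at least 101-fold, 56.5-fold and 51.8-fold higher. Without TG DSS 22 these 4 bounds were 78.3-fold for Mmp8, 11.6-fold for Ngp, 17.9-fold for Il22 and 31.0-fold for Tarm1. Cxcl2 and Cxcl3 had 2 counts each in controls and ratios of 862 (238 to 7126) and 250 (68.7 to 2068). Il6 had 3 and a ratio of 216 (73.6 to 1052). Without TG DSS 22 the ratios were 469 (129 to 3882) for Cxcl2, 148 (40.5 to 1233) for Cxcl3 and 86.7 (29.2 to 425) for Il6. Without TG control 14, Cxcl2 and Cxcl3 had 0 counts in controls and were at least 411-fold and 119-fold higher. S100a9 rose by 8.23 (SE 0.92, edgeR adjusted p = 4.03e-05), S100a8 by 8.10 (SE 0.86, adjusted p = 2.71e-05) and the macrophage lectin Chi3l3 (chromosome 3, 106147554 to 106167564) by 8.11 (SE 0.97, adjusted p = 6.43e-05). The trefoil peptide gene Tff2 (chromosome 17, 31141062 to 31144282) fell from 2.12 ± 1.28 to 0.119 ± 0.110 CPM, a log2 change of -4.07 (SE 0.61, adjusted p = 0.000361). Nxpe2 (chromosome 9, 48318004 to 48340898) fell from 168 ± 51.5 to 28.4 ± 17.6 CPM, a log2 change of -2.57 (SE 0.39, adjusted p = 0.000379). The other lower genes were the fucosyltransferase Fut9 at -3.11, Alb at -2.88, the peptidase Mme at -2.84, the dioxygenase Tdo2 at -2.51, the lipid desaturase Scd1 at -2.51, Fmod at -2.48, Pla2g3 at -2.45 and Cyp2c69 at -2.32, with adjusted p from 0.000462 to 0.0103. Without TG control 11, Scd1 was at -1.45, Alb at -2.17 and Mme at -2.13, and without TG DSS 21, Tff2 was at -4.70 and Pla2g3 at -3.06. Without TG DSS 22, S100a9 was at 7.32, S100a8 at 7.14 and Chi3l3 at 7.40, and without TG control 13, Chi3l3 was at 8.87. Apart from Ngp, which passed in 2 of 8 fits that left out 1 library, the named genes passed in all 8. Of its 260 counts most came from TG DSS 22, at 7.67 CPM against at most 0.652 CPM in the other TG DSS libraries.

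Between DSS and control, 4029 genes differed in TG mice, 2401 higher and 1628 lower, of which 1014 and 231 by at least 2-fold. The groups did not overlap in 4677 genes (28.0%), against 2.86% by chance. Both STAT3 targets and antimicrobial defence passed with an estimated correlation. STAT3 targets had 14 of 16 higher over all genes (median 1.92, camera adjusted p = 1.47e-21, or 0.0128 with an estimated correlation), and antimicrobial defence 11 of 17 higher, such as Saa3 at 6.34 (median 2.04, 6.50e-12 and 0.00502). Called by camera and fry but not with an estimated correlation were interferon-gamma targets (18 of 21 higher, median 1.10, 6.50e-09 and 0.209), class II presentation (7 of 7, median 1.18, 5.12e-10 and 0.0867), cytokines (19 of 21, median 3.95, 7.05e-21 and 0.0575), neutrophils (11 of 12, median 5.71, 5.01e-14 and 0.0692) and macrophages (15 of 16, median 1.54, 2.71e-19 and 0.0575). B cell genes had 12 of 15 higher, with Cd22 at 2.29 and Ccr7 at 3.93 (median 2.19, 3.54e-08 and 0.210). Red blood cells had 5 of 5 higher (median 2.88, 1.87e-09 and 0.0575), endothelium 9 of 12 (median 0.83, 2.76e-07 and 0.210) and enteric neurons and glia 8 of 14 (median 0.75, 7.32e-05 and 0.297). Adjusted over the list alone, these counts were 14, 13, 18, 7, 20, 12, 15, 13, 5, 11 and 10, and in antimicrobial defence 1 gene was then lower.

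Also higher by camera and fry, but not with an estimated correlation, were IL-10 family genes (6 of 10, median 1.01, adjusted p = 0.00202 and 0.119), T and NK lymphocytes (9 of 23, median 0.95, 5.62e-06 and 0.1902), mast cells and eosinophils (5 of 11, with 1 lower, median 1.34, 0.00407 and 0.1902), regenerating epithelium (6 of 14, median 0.57, 2.54e-06 and 0.0692), matrix remodelling (9 of 19, median 0.63, 5.19e-07 and 0.299) and immediate early genes (6 of 12, median 0.47, 0.00467 and 0.322). Lower by camera, of which fry did not call the last pair (0.0941 and 0.134), were absorptive colonocytes (7 of 20, median -0.53, 0.000259 and 0.111), crypt stem cells (7 of 13, with 2 higher, median -0.81, 0.00190 and 0.223), proliferation (0 of 20 called, all below 0, median -0.62, 0.000259 and 0.499) and cholesterol biosynthesis (2 of 20, median -0.39, 0.00202 and 0.544). Adjusted over the list alone the counts were 8, 12, 6, 7, 10 and 6 higher and 9, 8, 0 and 0 lower. The proliferation score was 2.65 in TG DSS 20 and 4.20 to 5.19 in the other TG DSS libraries, against 4.99 to 5.34 in TG controls. Fatty acid oxidation (median -0.25, 0.0118) reached 0.0884 without TG DSS 21, and xenobiotic metabolism (median -0.30, 0.0165) 0.0526 and 0.0597 without TG DSS 21 and TG DSS 22. Smooth muscle (median -0.19, 0.0445) reached 0.143, 0.141, 0.184, 0.103 and 0.123 without TG control 11, TG control 12, TG DSS 19, TG DSS 21 and TG DSS 22. Adipose tissue (median -4.95, 0.0362) reached 0.185, 0.0715, 0.0573, 0.103 and 0.0572 without TG control 11, TG control 13, TG DSS 19, TG DSS 21 and TG DSS 22. Goblet cells (median 0.46, 0.0570), tuft cells (median 0.39, 0.0580), plasma cells (0.485), the unfolded protein response (0.314), pancreas (0.332), small intestine (0.465), posterior (0.465) and circadian clock genes (0.701) were not called. With an estimated correlation fatty acid oxidation, xenobiotic metabolism, smooth muscle and adipose tissue had adjusted p of 0.499, 0.465, 0.638 and 0.573. Type I interferon-stimulated genes (median -0.12, mean -0.14), enteroendocrine genes (-0.10 and -0.02) and tight junctions (0.03 and 0.03) were not called (0.973, 0.911 and 0.903) and differed in sign from their test. With 1 library left out, camera called type I interferon-stimulated genes (0.0184 without TG control 14), goblet cells (0.0212 without TG control 14, 0.0188 without TG DSS 20, 0.0095 without TG DSS 22) and tuft cells (0.034 without TG control 14, 0.00649 without TG DSS 20, 0.0262 without TG DSS 22). It then also called unfolded protein response (0.0451 without TG DSS 20). The receptor genes Il10ra, Il20ra and Il10rb rose by 1.33 (adjusted p = 9.16e-05), 2.71 (adjusted p = 0.0189) and 0.34 (adjusted p = 0.00390).

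The interaction asked whether the response to DSS differed between genotypes, and no single gene passed by edgeR. An unadjusted p below 0.05 was found for 1350 genes, DESeq2 called 35 genes and limma-voom 0, and without TG control 14 edgeR called 1. Genes with the smallest edgeR p, chosen after their values were seen, were Clps, Ang4, Cwh43, Itln1 and Mptx1, each with an adjusted p of 0.307. Ang4 changed by -4.65 with DSS in WT and by 2.04 in TG mice, Itln1 by -4.90 and 3.24, and Mptx1 by -6.12 and -0.80. By DESeq2 the adjusted p was 6.05e-06 for Ang4 and Clps, 1.96e-05 for Itln1 and 1.99e-05 for Mptx1. Camera called 16 of 36 lists, and with an estimated correlation and by fry 0 passed. The strongest were interferon-gamma targets, with a smaller rise in TG mice (21 of 21 below 0, 8 adjusted over the list alone, median -1.04, adjusted p = 1.70e-14, or 0.315 with an estimated correlation), and B cells, with a larger one (15 of 15 above 0, 3 adjusted over the list alone, median 1.66, 5.04e-11 and 0.318). Proliferation genes (20 of 20 below 0, median -0.90, 3.06e-08 and 0.513) and goblet cell genes (12 of 15 above 0, 4 adjusted over the list alone, median 0.32, 1.99e-05 and 0.315) followed. The proliferation score was 2.65 in TG DSS 20, against 4.20 to 5.19 in the other TG DSS libraries. With 1 library left out that list's camera adjusted p was at most 1.78e-05.

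The other lists called by camera for the interaction were higher for tuft cells (median 0.51, adjusted p = 5.69e-05, or 0.315 with an estimated correlation), small intestine (0.76, 0.000171 and 0.315), enteric neurons and glia (0.65, 0.000300 and 0.513), smooth muscle (0.46, 0.000439 and 0.554), endothelium (0.40, 0.000546 and 0.554), red blood cells (0.88, 0.00399 and 0.513), xenobiotic metabolism (0.19, 0.0158 and 0.554) and antimicrobial defence (0.04, 0.0397 and 0.474). They were lower for adipose tissue (-5.23, 0.000117 and 0.513), cholesterol biosynthesis (-0.35, 0.000431 and 0.584), type I interferon-stimulated genes (-0.88, 0.000472 and 0.592) and regenerating epithelium (-0.47, 0.00399 and 0.474). Type I genes reached 0.333 without TG control 14, regenerating epithelium 0.0910 without WT DSS 6 and cholesterol biosynthesis 0.0534 without TG DSS 20. Xenobiotic metabolism reached 0.177, 0.376 and 0.0534 without TG control 11, WT DSS 10 and TG DSS 20. Antimicrobial defence reached 0.162, 0.116, 0.0636, 0.0532, 0.113 and 0.117 without WT control 3, WT control 4, TG control 12, WT DSS 6, WT DSS 7 and WT DSS 10. Not called were IL-10 family genes (0.780), STAT3 targets (0.439), class II presentation (0.340), neutrophils (0.667), macrophages (0.780), T and NK lymphocytes (0.497), plasma cells (0.0524), mast cells (0.128), absorptive colonocytes (0.204), crypt stem cells (0.971), the unfolded protein response (0.483), matrix remodelling (0.971), pancreas (0.348), posterior genes (0.0891), circadian clock (0.437) and immediate early genes (0.602). Cytokines (median -0.05, mean 0.03), tight junctions (-0.01 and 0.01), fatty acid oxidation (-0.0075 and 0.0091) and enteroendocrine genes (-0.18 and -0.06, with a test of the opposite sign) were not called (0.550, 0.971, 0.971 and 0.971). With 1 library left out, camera called class II presentation (0.00493 without WT DSS 7), cytokines (0.0369 without TG DSS 22) and macrophages (0.00401 without WT DSS 10). It then also called T and NK lymphocytes (0.0324 without TG control 14), plasma cells (0.0377 without WT control 1, 0.0476 without WT control 2, 0.0307 without WT control 3, 0.0168 without TG control 11, 0.0433 without TG control 14, 0.0122 without WT DSS 6, 0.000671 without TG DSS 20) and mast cells (0.0177 without TG DSS 22). Called in such fits too were absorptive colonocytes (0.0476 without TG control 13, 0.0262 without TG DSS 22), unfolded protein response (0.0103 without WT control 4) and posterior genes (0.0123 without WT control 4, 0.0217 without TG control 12, 0.0262 without WT DSS 10). The rest were circadian clock (0.0148 without TG control 14, 0.05, below the limit before rounding, without WT DSS 10).

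Across genes, the log2 effects of the transgene without and with DSS had a Pearson r of 0.227 and a Spearman rho of 0.268, with the same sign in 58.3% of 16693 genes. Genes are not independent replicates. H2-Eb1, Cd52 and Il2rg were lower in both TG comparisons, 3 genes against 0.0683 if the calls were independent. Of the 38 genes called without DSS, 38 had the same sign with DSS, and of the 37 called with DSS, 32 had the same sign without. The effects of DSS in WT and TG mice had a Pearson r of 0.758 and a Spearman rho of 0.626, with the same sign in 72.6% of genes. Both genotypes shared 1357 higher genes, against 261.49 if independent, and 626 lower genes, against 111.86, and 1 gene was called in opposite directions. The correlation of transgene effects ranged from 0.145 to 0.366 when 1 library was left out, and that of DSS effects from 0.691 to 0.770.

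**Figure D4:**
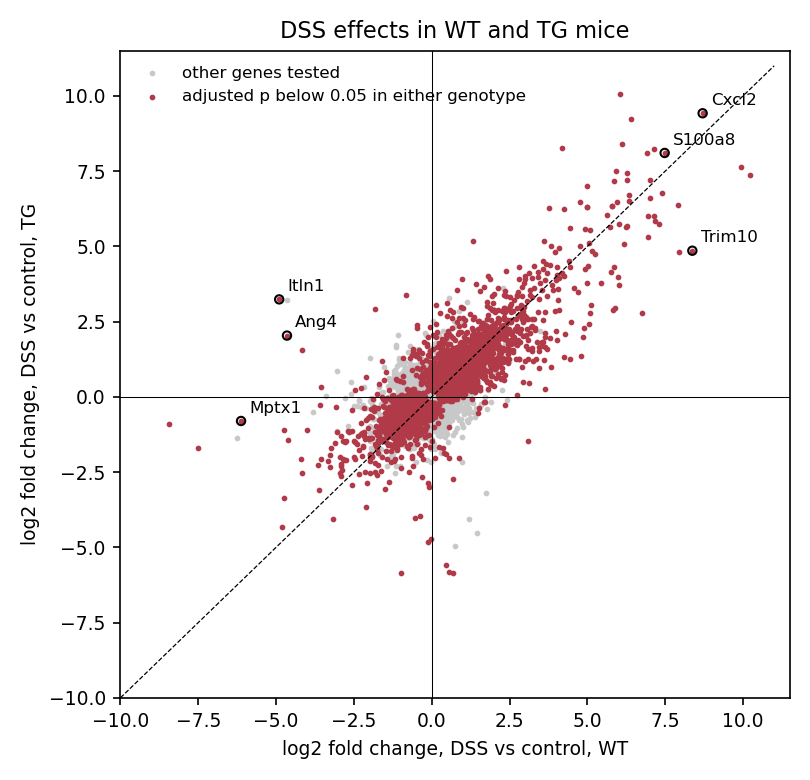
Log2 fold change with DSS in WT mice (horizontal axis) against TG mice (vertical axis), 1 point per tested gene, red where the adjusted p was below 0.05 in either genotype, with a dashed line of equality. The effects had a Pearson r of 0.758 across genes.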

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

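Of the tests of the lower B cell and follicle genes in TG controls, those for sex and time of day were chosen after seeing the result, and that for follicles before. The list score differed by -2.67 (pooled SD 0.610), by -2.469 (0.591) without the libraries lacking Xist and by -2.813 (0.284) without those with Dbp above Arntl. This argues against sex and time of day as the whole cause. Both settings left out WT control 4, and the second also left out TG control 14, the TG control nearest to WT. Groups that do not overlap cannot come to overlap with fewer libraries, so only the size of the difference was tested. Fewer lymphoid follicles in the tissue piece remain open: within the DSS groups the 34 called genes outside the list had a median correlation of 0.4665 with the list score, against a 95th percentile of 0.312 for random genes. The correlations ranged from -0.79 to 0.98, and the test does not separate fewer follicles in the piece from fewer B cells in TG mice. The amount of muscle and fat in the piece stays open too. Of 38 genes, 1 was called with the smooth muscle covariate and 6 with the adipose covariate. TG control 14, with the lowest adipose score (-1.04), had the highest B cell score of the TG controls (0.87). WT control 4 had the lowest adipose and highest B cell score of WT controls (-0.98 and 3.11). The same held for WT DSS 6 among WT DSS libraries. TG DSS 20 had the highest adipose and lowest B cell score of TG DSS (2.98 and 0.79). Other libraries go the other way. WT control 3, TG control 11 and WT DSS 7 had their group's highest adipose score (3.63, 6.84 and 3.33). Their B cell scores (2.42, -0.13 and 2.92) were not the lowest of their groups. TG DSS 21 had the lowest adipose score of TG DSS (-0.88) but not the highest B cell score (1.99).

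For the lower interferon-gamma targets in TG DSS, all tests were chosen after seeing the result. The score differed by -1.246 (pooled SD 0.481) and by -0.8726 (0.283) without WT DSS 10, which argues against a single WT library. The DSS rise was smaller in TG than in WT by 46.1% for interferon-gamma targets (35.6% to 52.7% with 1 library left out), while the share had no settled sign for neutrophils (2.22%, from -4.95% to 12.02%), cytokines (7.88%, from -0.375% to 17.5%), STAT3 targets (2.22%, from -3.74% to 11.2%), class II presentation (12.8%, from -7.39% without WT DSS 10 to 25.4% without WT DSS 7) and macrophages (-3.56%, from -22.7% without WT DSS 10 to 4.62% without WT DSS 6). Milder inflammation as a whole stays open: the largest share of neutrophils, cytokines and STAT3 targets was 0.171 times that of interferon-gamma targets, at most 0.3826 with 1 library left out, but the 3 lists stayed below 0.5 times that share by only 20.8 (SE 12.5), 15.2 (SE 12.98) and 20.8 (SE 16.1) percentage points, less than the 2 SE set for the test. A first measure, the gap between TG and WT after DSS over the WT rise, also counted the difference in controls and reached 0.5167. The neutrophil and cytokine shares average unlike TG DSS libraries. Neutrophil scores were 1.34 and 1.39 in TG DSS 19 and 21, 2.81 and 3.55 in TG DSS 20 and 22, and 2.62 to 3.22 in WT DSS. Cytokine scores were 1.26 and 1.10 in TG DSS 19 and 21, 2.61 and 3.07 in TG DSS 20 and 22, and 2.54 to 2.80 in WT DSS.

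Ang4, Itln1 and Mptx1 were lower in all WT DSS than in all TG DSS libraries. Mptx1 in TG DSS (367.9 to 1299 CPM) was also below all WT controls (1416 to 7770 CPM). For these 3 genes the goblet cell tests were chosen after seeing the result and the gene copy test before. The smallest TG effect of the 3 genes after DSS (Mptx1, 3.805, SE 0.79) exceeded the largest of the goblet list (Clca3, 1.91, SE 0.48) by 1.893, below the bound of 2.53, and with Clca1 matched by symbol Capn9 (0.84, SE 0.26) was largest and the difference 2.96 exceeded its bound of 2.10. The list median of 0.42 (SD of members 0.47) lay 3.39 below Mptx1, with either match, so the list as a whole moved less than these genes. The 3 genes were picked among those with the smallest interaction p, so a gap to an unselected list was likely from the start. The test therefore cannot decide on goblet cell content, which stays open. Whether milder inflammation in some TG DSS libraries plays a part was not tested for these genes. TG DSS 19 and 21, with the lowest neutrophil scores of the DSS libraries, had 1687 and 2311 CPM of Ang4 and 66.7 and 97.65 CPM of Itln1. TG DSS 20 and 22 had 671.5 and 495.2 CPM of Ang4 and 5.635 and 16.37 CPM of Itln1. The WT DSS libraries had at most 44.39 CPM of Ang4 and 1.26 CPM of Itln1. Reads shared between gene copies stay open too, since 0 of the 3 genes had only whole counts (66.7%, 93.3% and 60.0% of the values were whole).

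The splits of libraries were set before the result was seen. For TG against WT in controls 1 of 35 splits, the real one, reached 38 genes and the highest other 1. This is the smallest share that 35 splits can give, so chance is unlikely at that level but not excluded. By unadjusted p below 0.05, 3 of the 34 other splits gave at least the 1095 genes of the real one. After DSS 2 of 35 reached 37, and the highest other was 229, for WT DSS 10, TG DSS 20 and TG DSS 22 against the rest, so chance cannot be excluded and the libraries have a structure other than genotype. For DSS in WT 1 of 35 reached 2965 (highest other 834) and in TG 1 of 35 reached 4029 (highest other 0). Each was the real split and again the smallest share possible, so chance is unlikely for both. For the interaction 19 of 100 draws reached 1350 genes with an unadjusted p below 0.05 (highest other 2722), so chance cannot be excluded. For the correlation of TG effects 6 of 100 reached 0.2267 in size (highest other -0.3268), so chance cannot be excluded. For DSS effects 1 of 100, the real one, reached 0.7584 (highest other 0.6997), so chance is unlikely.

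Single outlying libraries were sought with the Dixon test set before the result was seen, in 295 groups. It flagged 24, where chance flags about 1 in 20 groups, or 14.75. Only groups with 4 libraries were tested, so the 3 WT DSS libraries were not. The lack of flags there does not mean that none stood apart. In WT DSS 10, for example, Ddx3y was at 66.2 CPM, and in the other WT DSS libraries at 0. Among lists, type I interferon-stimulated genes were at 5.094 in WT control 3, neutrophils at -0.8176 in WT control 4, the unfolded protein response at 6.146 and posterior genes at 4.329 in TG DSS 20, and small intestine genes at 2.009 in WT control 2 (mean log2 CPM). Among genes, in CPM, WT control 4 stood apart for Ddx3y (57.92), Treml2 (3.259) and Prss22 (0.02649), and WT control 2 for H2-Q7 and H2-Q9 (8.536) and Hemt1 (0.02676). TG control 14 stood apart for Cd22 (3.021), Socs1 (3.994), Cxcl2 and Cxcl3 (0.04993) and Tff2 (4.019), and TG DSS 20 for Socs1 (5.049) and AB099516 (1.01). TG DSS 22 stood apart for Ngp (7.667) and Il22 (3.576), WT control 3 for Socs1 (4.748), TG control 11 for Tdo2 (3.377), TG control 12 for Hemt1 (0.02692) and TG control 13 for Mptx2 (0.1294). For Ddx3y, Prss22, Hemt1, Cxcl2 and Cxcl3 the other libraries of the group were at 0. The test then flags any count at all, and H2-Q7 and H2-Q9 are 1 measurement flagged under both names. The 24 flags are therefore not an excess over 14.75 that can be read.

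The DSS response differed between genotypes by camera in 16 lists, a test set before the result was seen, and in 0 with an estimated correlation. The adjusted p was 1.70e-14 for interferon-gamma targets, 5.04e-11 for B cells, 3.06e-08 for proliferation, 1.99e-05 for goblet cells, 5.69e-05 for tuft cells, 0.000117 for adipose tissue, 0.000171 for small intestine and 0.000300 for enteric neurons and glia. It was 0.000431 for cholesterol biosynthesis, 0.000439 for smooth muscle, 0.000472 for type I interferon-stimulated genes, 0.000546 for endothelium, 0.00399 for red blood cells and for regenerating epithelium, 0.0158 for xenobiotic metabolism and 0.0397 for antimicrobial defence. Without the libraries lacking Xist, a setting chosen after seeing the data, 17 lists were called, 13 of them among these 16, and type I interferon-stimulated genes (0.0825), antimicrobial defence (0.259) and xenobiotic metabolism (0.28003) were not. Age, litter and cage were not tested.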

How the results depend on the processing

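Of the settings below, the adipose covariate, the fits without the libraries lacking Xist or with Dbp above Arntl and that with identical genes taken once were chosen after seeing the data. Other scalings, filters and the robust dispersion kept every count of genes within 1.5-fold, and fixed alternatives kept 42 of 54 such counts; for the rest the cause was not tested. For TG against WT in controls (38 genes), DESeq2 gave 195, limma-voom 2, the Xist covariate 20, the smooth muscle covariate 1, a surrogate variable 73, the adipose covariate 6 and the fit without libraries lacking Xist 13. After DSS (37) they gave 832, 95, 11, 10, 98, 102 and 9, only the 2 groups compared gave 5, and leaving out libraries with Dbp above Arntl 23. That last setting gave 1974 genes for DSS in WT, and for the interaction (0) DESeq2 gave 35 and the adipose covariate 1. Without 1 library the counts were 1 to 35, 8 to 79, 2313 to 2632 (DSS in WT), 2958 to 4139 (DSS in TG) and 0 to 1. The lists called fell with an estimated correlation to 2, 0, 9, 2 and 0, and by fry to 3, 7 and 0 for both TG comparisons and the interaction. Without 1 library they were 11 to 19, 16 to 23, 19 to 21, 21 to 28 and 15 to 19. Correlations were 0.145 to 0.366 for TG and 0.691 to 0.770 for DSS effects without 1 library, and 0.792 for DSS effects of genes with at least 5 CPM. Reversed were type I interferon-stimulated genes in controls, at an adjusted p of 1.04e-06 without libraries with Dbp above Arntl and 0.000434 without TG control 14. With 1 library left out that list ranged from 5.58e-08 (without WT control 3, higher) to 0.991 (without WT control 1). Without libraries with Dbp above Arntl, monocytes and macrophages after DSS (0.0285), type I interferon-stimulated genes in the interaction (0.675) and matrix remodelling in the interaction (0.0210) also reversed. Under fixed alternatives a named gene stayed on its side of the threshold, called or not, in 8035 cases, lost its call in 156 and gained one in 133. These cases include genes never called, such as all those of the interaction, which cannot lose a call. They therefore do not give the share of calls lost. For TG against WT, 0 of the 10 lower genes in controls, 0 of the 6 higher and 2 of the 10 lower genes after DSS were called in all settings. The alternative without immunoglobulin, T cell receptor and mitochondrial genes was not run, and the fit to only the groups compared was not run for the interaction. At this spread and depth, 1.5-fold changes simulated without structure shared between genes were recovered in at most 38.8% of genes.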

Other observations

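Ifng, the gene of interferon-gamma itself, was below the filter and not tested, and was looked at after the values of its targets were seen. It had 44 counts in 3 WT DSS libraries (17, 6 and 21) and 3 in 4 TG DSS libraries (0, 1, 0 and 2), a rate ratio of 15.8 (exact interval 5.07 to 79.6, counting error only). Without TG DSS 22, which held 2 of those 3 counts, the ratio was 35.5 (exact interval 6.05 to 1435), and without any other DSS library it was 11.6 to 19.3. WT controls had 9 counts and TG controls 4.

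Epithelial defence genes varied between libraries of 1 group. Reg3b, an antimicrobial lectin, was at 341.5 CPM in WT DSS 10 against 5093 and 5508 CPM in the other WT DSS libraries, and Reg3g at 70.32 against 1152 and 891.3 CPM. Ang4 in controls ranged from 145 to 1437 CPM in WT and from 68.2 to 714 CPM in TG mice. After DSS it was at 20.9, 44.4 and 34.0 CPM in WT and at 1687, 672, 2311 and 495 CPM in TG mice. Retnlb, a goblet cell product, was at 182, 205 and 150 CPM in WT DSS and at 775, 163, 1503 and 448 CPM in TG DSS.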
